A study of Oryza sativa with 7 samples.

How the data were processed

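RNA was measured in 7 libraries from the stem base of IR64 rice seedlings, 6 days old: crown root primordia at initiation (replicates 1, 2 and 3), primordia at outgrowth (replicates 1 and 2) and control ground tissue (replicates 1 and 2), all collected by laser capture microdissection. Per the labels' protocols, RNA was isolated with the PicoPure kit and libraries were made with a SMARTer low-input kit, which amplifies cDNA from small amounts of RNA. Reads were aligned with STAR, per the submitters' processing notes, and its version, the counting tool, the genome build and the gene annotation are not given in the sources used here. Whether counting used strand is likewise not given, so reads of overlapping or antisense genes, or of near-identical copies, may be divided between genes.

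Each of the 7 deposited tables gives a gene identifier and a value headed FPKM, a count scaled for gene length and library total. The deposited values were read as counts of reads per gene, because they are whole numbers of at least 1 with totals of 8351775 to 25448025. FPKM values with such totals would need an expression-weighted mean transcript length of 39.3 to 119.7 bases. The tables list no 0 values, so a gene missing from a table was taken to have 0 reads there. Over all tables there were 24775 identifiers, 24728 of the form LOC_Os and 47 of the form fgenesh. None matched the reference table of assembly ASM3414082v1, so no gene names were used, and gene lists of pathways and tissue markers fixed before the data were examined could not be applied. Chromosomes and the order of genes were read from the locus identifiers.

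The design fixed before the data were examined assumed FPKM and planned limma on log2 values. As the values are counts, the test was changed to edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, glmQLFit and glmQLFTest) with TMM scaling and an abundance trend of the dispersion. Initiation replicates 1 and 3 were averaged and rounded into 1 sample, giving 6 libraries with 2 per group. All 6 libraries entered a joint fit of group means, which left 3 residual degrees of freedom and 4.72 prior degrees of freedom, with a common biological coefficient of variation of 0.374. The planned filter was carried over to CPM, counts scaled to a library total of 1000000: genes with at least 1 CPM in at least 2 libraries were tested, 18830 in all. The comparisons were initiation with control, outgrowth with control, outgrowth with initiation, and the equally weighted mean of both stages with control. p-values are two-sided and were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the fold change and its F statistic. CPM values use the TMM-scaled library totals.

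The labels do not tie libraries to plants. The p-values measure only the spread between these libraries, which may be technical, and may be too small if libraries of a group share plants. How cells were chosen for capture is given only by stage and tissue.

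The planned rule for named genes asked for a gene name or product, which could not be applied. It became the 2 genes with the largest fitted log2 difference per direction and comparison, among those with an adjusted p below 0.05, no overlap of libraries between the groups and a mean of at least 5 CPM in the higher group. The rule was met by 2472 genes higher and 2779 lower at initiation than in control, 2151 and 2445 at outgrowth, and 208 and 342 between the stages. Where a group had no read, the fold is a lower bound against 3 counts over the group, which is 0.0863 CPM in control, 0.0992 CPM at initiation and 0.126 CPM at outgrowth. The floor of a single library is between 0.115 CPM in control replicate 2 and 0.347 CPM in control replicate 1 on the same scale. Where a group had few reads, the ratio of pooled counts has an exact conditional binomial 95% interval. The reads carry no molecular identifiers as far as the sources say, so floors and intervals cover counting error only. The deeper libraries give the more precise low values.

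The test was run on simulated counts drawn with the real means, library sizes and dispersions, with 67, 67 and 66 genes changed by 2-fold, 4-fold and 8-fold. For initiation with control it recovered 13.4%, 49.3% and 68.2% of them, with 6 false calls among 18399 genes. For outgrowth with control it recovered 1.49%, 43.3% and 62.1%, with 9 false calls among 18334 genes. For outgrowth with initiation it recovered 2.99%, 49.3% and 63.6%, with 3 false calls among 18334 genes. Genes with a 2-fold change were thus mostly missed in these simulations. Far more genes were called against control in the data, 5729 at initiation and 4976 at outgrowth. The adjusted threshold was less strict there, so the recovered shares do not carry over to those comparisons.

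Alternatives fixed before the data were examined were other pseudocounts (limma 3.58.1 on log2 CPM), other filters, quantile scaling (with limma on log2(CPM + 1), so the test changes too), median-ratio and library-total scaling, only the groups compared, library quality weights with limma-voom, no abundance trend, a replicate block, a 2-fold minimum, and leaving out each library. Added after the data were seen were limma on log2(CPM + 1), DESeq2 1.42.0, and initiation replicates 1 and 3 as separate libraries. So were libraries thinned to the smallest total and a control library of its own for each stage. Of these, limma on log2(CPM + 1) comes nearest to the planned main test, which was limma on log2(FPKM + 1).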

Results

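Crown roots are the shoot-borne roots that make up most of the root system of rice, and they arise from primordia inside the stem base. Expression was measured by RNA sequencing in crown root primordia of the indica rice cultivar IR64, cut from the stem base of seedlings 6 days old by laser capture microdissection, in which chosen cells are excised from a tissue section under a microscope. The series held 7 libraries: 3 of primordia at initiation, 2 of primordia at outgrowth and 2 of ground tissue, the control. Total counts were 11411697, 15013634 and 21043491 in initiation replicates 1, 2 and 3. They were 12517569 and 11337620 in outgrowth replicates 1 and 2, and 8351775 and 25448025 in control replicates 1 and 2. Between 18597 genes in control replicate 1 and 22185 genes in outgrowth replicate 1 had at least 1 read. The most abundant gene took between 0.721% of the counts in initiation replicate 2 and 1.97% in control replicate 2. Genes are given by the identifiers in the files, which do not pair them with gene names, and none of the 24775 identifiers matched the reference table used here.

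Initiation replicates 1 and 3 differed by less than the sampling noise and were counted as 1 sample, the mean of both. The squared difference between them averaged 0.400 times the binomial counting noise, against 27.5 times for initiation replicates 1 and 2, 9.08 times for the outgrowth pair and 50.1 times for the control pair. Each group therefore had n = 2. On log2(CPM + 1) values, where CPM is counts scaled to a library total of 1000000, the Pearson correlation across genes within a group was 0.963 for initiation, 0.988 for outgrowth and 0.919 for control. It lay between 0.904 and 0.939 for pairs of libraries from the different stages and between 0.735 and 0.795 for pairs of a primordium and a control library. Genes are not independent replicates, and these correlations describe the libraries only. The median absolute log2 difference between the libraries of a group, over 12367 genes, was 0.15 at outgrowth, 0.29 at initiation and 0.41 in control. Principal component 1, with 65.5% of the variance, separated control from the primordia, and component 2, with 18.5%, separated outgrowth from initiation.

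**Figure D1:**
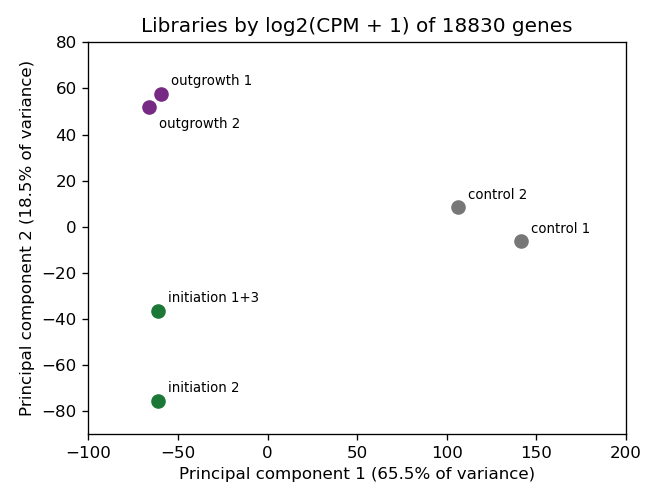
Each point is a library placed by its first principal components of log2(CPM + 1), with the share of variance on each axis; initiation replicates 1 and 3 are averaged into 1 point. The control libraries lie apart along component 1 (65.5% of the variance) and the stages lie apart along component 2 (18.5%).

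**Figure D2:**
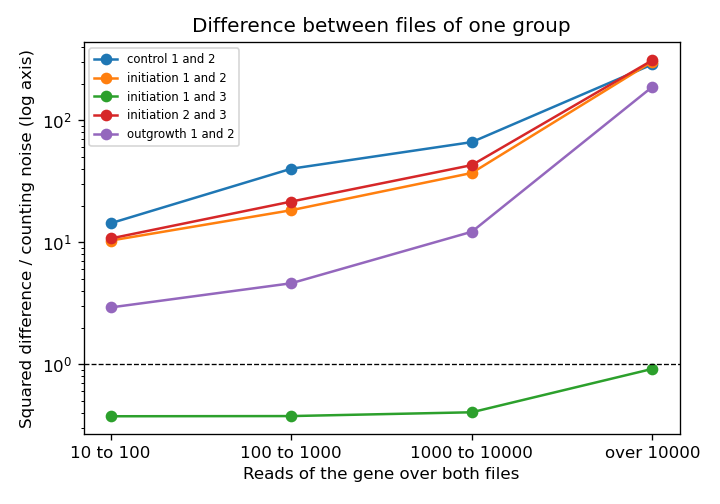
Mean squared difference between the libraries of a group, divided by binomial counting noise (log axis), against the number of reads of a gene over both libraries. Initiation replicates 1 and 3 lie below the dashed line at 1 in each class of read number, from 0.376 at 10 to 100 reads to 0.919 over 10000 reads, and each other pair lies above it.

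The comparison of initiation with control addressed which genes distinguish a forming primordium from the ground tissue. LOC_Os02g40070 had 378 ± 69.3 CPM at initiation (SD, n = 2) and no read in control, at least 4379-fold higher against a floor of 3 counts over the control group (edgeR adjusted p = 5.14e-05). Such bounds, here and below, cover counting error only. Of 17559 genes with at least 10 reads expected in control replicate 1, 699 had none, so the bounds may be too high. LOC_Os11g14570 had 270 ± 22.3 CPM at initiation (SD, n = 2) and no read in control, at least 3131-fold higher (edgeR adjusted p = 0.000129). In the other direction, LOC_Os03g04220 had no read at initiation and 909 ± 457 CPM in control (SD, n = 2), at least 9164-fold lower at initiation (edgeR adjusted p = 0.000149). LOC_Os04g11390 had no read at initiation and 578 ± 79.2 CPM in control (SD, n = 2), at least 5832-fold lower (edgeR adjusted p = 0.000543). Of 18830 genes tested, 2704 were higher and 3025 lower at initiation at an adjusted p below 0.05 by edgeR's quasi-likelihood test. The median log2 fold change was 1.495 among the genes called higher and -2.30 among those called lower, with genes lacking a read in a group set at their bound or not. More than 8-fold differences, with those genes at their bound, were found for 581 genes called higher and 1155 called lower. Of the 516 most abundant genes, with a mean log2(CPM + 1) over 8 when initiation and control had equal weight, 242 were called higher and 65 lower, with a median log2 fold change of 0.56. The split differed with abundance: at a mean of 2 to 4, 412 were called higher and 856 lower, and under 2, 365 were called higher and 543 lower. The files of initiation and control had the same format. Without initiation replicate 2, 3076 genes were called. Without outgrowth replicate 1 or 2, which enter this comparison through the shared estimate of spread, 3807 and 3779 genes were called. The balance of directions was not fixed: more genes were called higher than lower without control replicate 2 (4607 and 3363), without control replicate 1 (3073 and 2834), with quantile scaling and limma (3519 and 3250) and with no low filter (3303 and 3290).

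The comparison of outgrowth with control put the same question to the later stage. LOC_Os06g31890 had 834 ± 150 CPM at outgrowth (SD, n = 2) and no read in control, at least 9667-fold higher (edgeR adjusted p = 8.79e-05). LOC_Os06g32240 had 535 ± 170 CPM at outgrowth (SD, n = 2) and no read in control, at least 6194-fold higher (edgeR adjusted p = 0.000140). The locus identifiers of this pair place them close together on chromosome 6, so reads may have been divided between related copies, and each level is uncertain to that extent. LOC_Os07g03250 had no read at outgrowth and 149 ± 4.92 CPM in control (SD, n = 2), at least 1183-fold lower at outgrowth (edgeR adjusted p = 0.00164). LOC_Os04g55590 had no read at outgrowth and 92.5 ± 18.3 CPM in control (SD, n = 2), at least 735-fold lower (edgeR adjusted p = 0.000140). In all, 2413 genes were called higher and 2563 lower at outgrowth, with median log2 fold changes of 1.61 and -2.26, unchanged with genes lacking a read in a group at their bound. Differences of more than 8-fold, with such genes at their bound, were found for 694 genes called higher and 957 called lower. Of the 462 genes with a mean log2(CPM + 1) over 8, outgrowth and control having equal weight, 203 were called higher and 61 lower, with a median log2 fold change of 0.47. At a mean of 2 to 4, 450 were called higher and 719 lower, and under 2, 424 were called higher and 316 lower. The outgrowth files differed in format from those of initiation and control, and a separate batch could not be told apart from the stage. Without outgrowth replicate 1 or 2 the count called fell to 1752 and 1523, and without control replicate 2 it was 7590. More genes were called higher than lower without control replicate 2 (4492 and 3098), without control replicate 1 (2682 and 2388), with quantile scaling and limma (3486 and 3138) and with no low filter (3011 and 2737). The same held narrowly with DESeq2 (3110 and 3095) and limma on log2(CPM + 0.1) (2751 and 2744).

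Many genes differed from control in the same direction at both stages. There were 1808 genes called higher at both stages and 1914 called lower at both, against 347 and 412 for independent lists of these sizes. LOC_Os02g40070 was among those called higher at initiation and had 368 ± 39.6 CPM at outgrowth (SD, n = 2), and the difference between the stages did not pass the test (edgeR adjusted p = 0.965). The log2 fold changes of all tested genes against control had a Pearson correlation across genes of 0.806 between the stages, and 83.1% had the same sign. Both comparisons share the control libraries. In 20 simulations of unchanged groups, all libraries were redrawn around the control means, with the same dispersion of a gene in each group. In the data the control pair had the widest spread, a median absolute log2 difference of 0.41 against 0.29 at initiation and 0.15 at outgrowth. The simulations leave this out and can understate what shared controls contribute. They gave a mean correlation of 0.489 and a same-sign share of 66.3%. They called 0 genes at both stages, which was set in advance because no gene was changed. That count cannot say how many shared calls come from the shared controls. The covariance was 4.67 against a simulated 0.311, a difference of 4.36. With a control library of its own for each stage, chosen after the data were seen and described without a test, the correlation was 0.647 in 1 arrangement and 0.589 in the other, the covariance 4.72 and 4.49, and the same-sign share 72.3% and 71.6%. Each comparison then rests on a single control library, and part of the excess in shared calls may come from the shared controls. Only 17 genes were called in opposite directions at the stages. Without outgrowth replicate 1 or 2, 1551 and 1350 genes were called in the same direction at both stages, against 3722 with all libraries, and 5877 without control replicate 2.

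**Figure D3:**
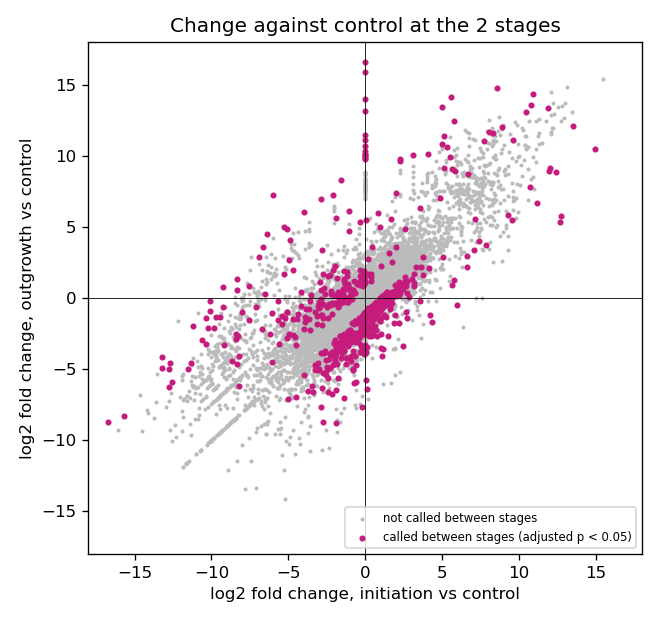
Each point is 1 of 18830 genes, at its fitted log2 fold change against control at initiation (x axis) and at outgrowth (y axis); the 580 genes called between the stages by edgeR are coloured. Genes without a read in a group form the line at 0 on the x axis and the outer streaks, where the fitted value is not a bound; 83.1% of genes have the same sign on both axes.

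The comparison of outgrowth with initiation asked which genes differ between the stages of the primordium. LOC_Os06g31890, with 834 ± 150 CPM at outgrowth (SD, n = 2), had no read at initiation and was at least 8414-fold higher at outgrowth (edgeR adjusted p = 0.00193). LOC_Os06g32240, with 535 ± 170 CPM at outgrowth (SD, n = 2), likewise had no read at initiation and was at least 5391-fold higher (edgeR adjusted p = 0.00312). LOC_Os01g12070 had 56.1 ± 36.2 CPM at initiation and 0.351 ± 0.383 CPM at outgrowth (SD, n = 2 each), a log2 fold change of -7.33 with a standard error of 0.91 (edgeR adjusted p = 0.0158). It had no read in control. LOC_Os01g10180 had 9.002 ± 3.85 CPM at initiation (SD, n = 2) and a single read at outgrowth, a ratio of 211 with a 95% counting interval of 37.6 to 8373 (edgeR adjusted p = 0.0156). Its control level was 10.3 ± 0.783 CPM (SD, n = 2). In all, 580 genes were called, 235 higher and 345 lower at outgrowth, with median log2 fold changes of 3.16 and -1.78, or 3.08 and -1.78 with genes lacking a read in a group at their bound. The split differed between classes of abundance, with both stages at equal weight. Under a mean log2(CPM + 1) of 2, 62 genes were called higher and 12 lower, at 2 to 4, 70 and 73, at 4 to 6, 48 and 131, at 6 to 8, 41 and 114, and over 8, 14 and 15. More genes were called higher than lower with limma on log2(CPM + 5) (561 and 511), limma on log2(CPM + 1) (536 and 496) and no low filter (784 and 739). The outgrowth libraries also listed more genes, 21737 and 21188 against at most 20935 in the others when thinned to the total of control replicate 1. Of these, 2537 and 2361 had 1 to 3 reads, against at most 1805 in the others.

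Set against control, the genes called between the stages fell into several patterns. Of the 235 genes higher at outgrowth than at initiation, 88 were lower than control at initiation and not called against control at outgrowth, and 66 were higher than control at outgrowth and not called at initiation. A further 46 were below control at both stages and 23 above it at both. Of the 345 genes lower at outgrowth, 116 were lower than control at outgrowth and not called at initiation, 93 were below control at both stages, 81 were above control at initiation and not called at outgrowth, and 32 were above it at both. LOC_Os11g14570 was above control at initiation and had 12.5 ± 5.43 CPM at outgrowth (SD, n = 2), lower than at initiation (edgeR adjusted p = 0.00605). LOC_Os03g04220, without a read at initiation, had 2.12 ± 0.485 CPM at outgrowth (SD, n = 2) against 909 ± 457 CPM in control (edgeR adjusted p between the stages = 0.0310).

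The calls between the stages depended on single libraries. The number of genes called was 15 without initiation replicate 2 (2182 at an unadjusted p below 0.05), 1821 without control replicate 1 and 1792 without control replicate 2, the control libraries entering through the shared spread. It was 0 by edgeR without outgrowth replicate 1 or 2, where 1446 and 1694 genes had an unadjusted p below 0.05. Without outgrowth replicate 1 or 2, LOC_Os01g12070 was no longer called (edgeR adjusted p = 0.130 and 0.102, within 1.03e-14 to 0.130 over its alternatives). Its ratio of initiation to outgrowth was then 87.5 (95% counting interval 42.4 to 218) and 684 (123 to 27045). Counting intervals take reads as independent and leave out the spread between libraries, so they do not show that the difference held. LOC_Os01g10180 was not called in these cases (edgeR adjusted p = 0.183 and 0.125) nor without initiation replicate 2 (edgeR adjusted p = 0.112), within 3.09e-05 to 0.183 over its alternatives. Its ratio was 99.1 (95% counting interval 17.6 to 3929) without outgrowth replicate 1 and 149.8 (26.3 to 5975) without initiation replicate 2. Without outgrowth replicate 2 it had no read left at outgrowth and was at least 37.5-fold lower there. With no abundance trend of the dispersion, none of these 4 genes was called, though their fitted log2 fold changes hardly moved (-7.48 for LOC_Os01g10180 and -7.33 for LOC_Os01g12070). The edgeR adjusted p was 0.0787 for LOC_Os06g31890, LOC_Os06g32240 and LOC_Os01g10180 and 0.0937 for LOC_Os01g12070. For LOC_Os06g31890 and LOC_Os06g32240 that p was the highest over the alternatives that tested them, and the lowest were 6.74e-25 and 1.68e-22. These 2 genes were not tested without outgrowth replicate 1 or 2, as they then reached 1 CPM in a single library, and LOC_Os01g12070 was not tested without initiation replicate 2 for the same reason. With all libraries, edgeR without the abundance trend called 0 genes (2997 at an unadjusted p below 0.05), DESeq2 called 1822 genes and limma on log2(CPM + 1) called 1032. Stage was confounded with the format of the files, so a batch cannot be told apart from the stage here.

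**Figure D4:**
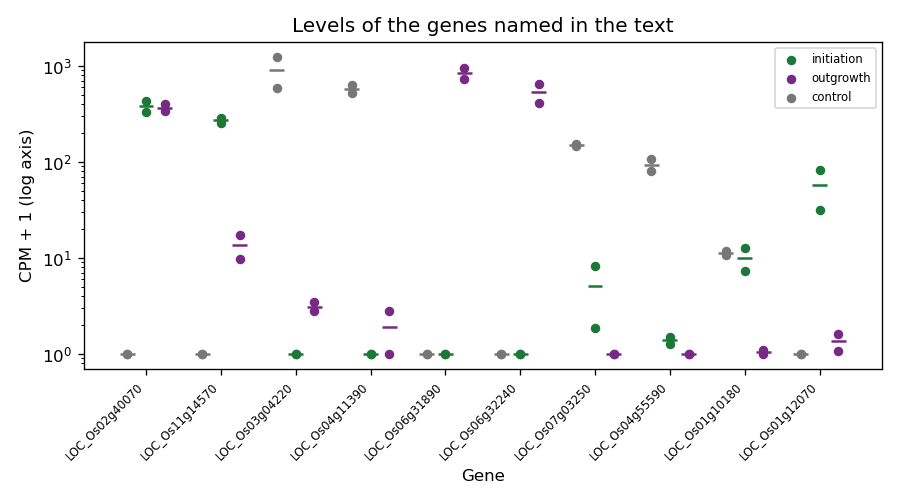
CPM + 1 (log axis) of the genes named in the text, for each library of control, initiation and outgrowth; points are libraries (n = 2 per group, initiation replicates 1 and 3 averaged), short lines are group means, and points at 1 are libraries without a read. LOC_Os06g31890 lies at 834 CPM on average at outgrowth and has no read in the other groups.

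The primordia of both stages, averaged with equal weight, were also compared with control. A gene changed at a single stage can pass this comparison, and 3722 genes were called in the same direction at both stages. Of the 18830 genes, 2900 were called higher and 3656 lower in primordia, with median log2 fold changes of 1.40 and -1.97, unchanged with genes lacking a read in a group at their bound. Without outgrowth replicate 1 or 2, 3871 and 3630 genes were called, against 6556 with all libraries. The balance turned without control replicate 2, with 4685 genes called higher and 3693 lower, and with quantile scaling and limma, with 4197 and 3685. A set of 42 genes had no read in control and at least 5 CPM in every primordium library, with a median of 32.9 CPM and a highest mean of 373 CPM over the primordia, where a floor of 3 counts over the control group is 0.0863 CPM. Conversely, 20 genes had no read in any primordium library and at least 5 CPM in both control libraries, with a median of 13.8 CPM and a highest mean of 31.8 CPM. At least 1 CPM in both libraries was reached by 16043 genes in control, 15991 at initiation and 16994 at outgrowth, and 14231 genes reached it in all 6 libraries.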

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

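The tests of differences between the stages were planned, and the test of a separate batch for outgrowth was chosen after the result was seen.

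Effects against control that differed between the stages were singled out where the stages themselves were tested against each other. There were 17 genes called in opposite directions against control at initiation and at outgrowth, 9 higher at initiation and lower at outgrowth and 8 the reverse. Each of the 17 was also called between the stages. This follows largely from the selection, because the stage effect is the difference of the 2 effects against control in the same fit. Among the named genes, LOC_Os11g14570 had 270 ± 22.3 CPM at initiation and 12.5 ± 5.43 CPM at outgrowth (SD, n = 2), with no read in control, and the stage difference had an edgeR adjusted p = 0.00605. LOC_Os03g04220 had no read at initiation and 2.12 ± 0.485 CPM at outgrowth (SD, n = 2), far below the 909 CPM of control (edgeR adjusted p = 0.0310 between the stages). LOC_Os06g31890 (edgeR adjusted p = 0.00193) and LOC_Os06g32240 (edgeR adjusted p = 0.00312) had reads only in the outgrowth libraries, higher there in 2 of 2. Of the 1990 genes called against control at initiation and not at outgrowth, 169 were called between the stages, and of the 1237 called at outgrowth and not at initiation, 182 were, so for the remainder a difference between the stages was not shown. These calls rest on single libraries and on the fit. Without outgrowth replicate 1 or 2, edgeR called 0 genes between the stages, with 1446 and 1694 at an unadjusted p below 0.05, and without initiation replicate 2 it called 15. With all libraries edgeR without the abundance trend called 0, with 2997 at an unadjusted p below 0.05, while DESeq2 called 1822 and limma on log2(CPM + 1) called 1032.

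The outgrowth libraries listed more genes than the others, also at low counts. Thinned to the total of control replicate 1, 8351775 reads, they listed 21737 and 21188 genes. The highest other library, control replicate 2, listed 20935, a gap of 253 at equal depth, so depth alone does not account for it. Control replicate 1 listed 18597, so the gap is small beside the spread within the control group. Genes with 1 to 3 reads numbered 2537 and 2361 in the outgrowth libraries, against at most 1805 in the others. A fixed share of control RNA in the outgrowth libraries was tested on 129 genes with at least 5 CPM in both controls and no read at initiation. Of these, 20 were absent at outgrowth where a single share of 1.20% of the control level predicts 4.87, a ratio of 4.11. That prediction takes reads as independent, yet 8 and 39 well-counted genes were absent from 1 outgrowth library of the pair where Poisson sampling gives 0.0041 and 0.0047, so the ratio decides nothing and a share of control RNA stays open. A separate batch for outgrowth and a difference in the tissue stay open too: 12 genes had at least 5 CPM in both outgrowth libraries and no read elsewhere, and batch and stage cannot be told apart because the differing file format covers outgrowth alone.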

How the results depend on the processing

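Limma on log2(CPM + 1), DESeq2, and initiation replicates 1 and 3 as separate libraries were chosen after seeing the data. So were thinned libraries and a control library of its own for each stage. Limma on log2(CPM + 1) comes nearest to the planned main test. Counts of genes called stayed within 1.5 times the main count in 20 of 23 alternatives for initiation with control, outgrowth with control and both stages alike, and in 20 of 22 for primordia with control, where only the groups compared gives no value. The exceptions left out a library. Over libraries left out, initiation with control ranged from 3076 to 7970, outgrowth with control from 1523 to 7590, primordia with control from 3630 to 8378, and genes in the same direction at both stages from 1350 to 5877. A lone library left in a group is assumed to vary like the other groups. For outgrowth with initiation, 580 in the main test, 9 of 23 alternatives stayed within that limit. The count was 1072 with limma on log2(CPM + 5), 1032 on log2(CPM + 1), 1523 with no low filter, 1169 with quantile scaling and limma on log2(CPM + 1), 1949 with only the groups compared, 2754 with quality weights in limma-voom, 1822 with DESeq2 and 1624 with replicates 1 and 3 separate. It was 0 with edgeR without the abundance trend, where 2997 genes had an unadjusted p below 0.05. Leaving out libraries gave 0 to 1821. The cause was not tested. The genes called higher there, 40.5% of calls, were 52.3%, 51.9% and 51.5% with the larger pseudocount, with log2(CPM + 1) and with no filter. With quantile scaling and limma, log2 fold changes against control moved by a median over genes of 0.13, 0.11 and 0.12 in initiation, outgrowth and all primordia. The correlation of fold changes between the stages, 0.806, was 0.647 and 0.589 with a control library of its own for each stage. Of 276 values of named genes under alternatives, 256 passed, 9 did not, all between the stages, and 0 reversed. The other 11 were not tested, because a left-out library put the gene under the filter: LOC_Os06g31890 and LOC_Os06g32240 without either outgrowth library, LOC_Os04g55590 without either control library and LOC_Os01g12070 without initiation replicate 2. With the replicate number as a block, 5136, 4401, 617, 5979 and 3317 genes were called, in the order initiation, outgrowth, stages, primordia and both stages alike. Deviations of libraries with the same number correlated at 0.024, 0.0072 and -0.027, with 2 pairs. No pairing was seen, but so few libraries cannot exclude it. The alternatives planned for gene lists were not run, as no list could be matched. Depth limits low genes most in control replicate 1, where 3 counts are 0.347 CPM.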

Other observations

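The tests of shared reads, independent libraries, lower depth and chromosome 6 were chosen after the result was seen.

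A run of neighbouring genes on chromosome 6 made up part of the outgrowth expression that was absent elsewhere. Of the 12 genes with at least 5 CPM in both outgrowth libraries and no read in the others, 4 lay between LOC_Os06g31890 and LOC_Os06g32240 in locus number, these included. They were all 4 of the genes tested in that stretch. Such genes pass the filter only through the outgrowth libraries, so this is partly set by the filter. Their means ranged from 19.3 to 834 CPM at outgrowth, and those of the other 8 genes from 7.51 to 76.7 CPM. All 12 were called between the stages by edgeR. The stretch was singled out after its values were seen.

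Genes whose level at outgrowth moved back toward control, or past it, were counted. There were 122 genes higher than control at initiation and lower at outgrowth than at initiation, against 49.5 for independent lists, and 142 with the reverse course, against 37.8. Of the 122 and the 142, 9 and 8 passed control and were called on its other side at outgrowth. Moves away from control in the same sense numbered 23 upward, against 33.7, and 93 downward, against 55.4. Both comparisons share the initiation libraries, which favours returns by chance alone. In simulations of unchanged groups the fold changes correlated at -0.497, against an observed -0.386. Their covariance was -0.318 in the simulations and -1.44 in the data. The correlation and the covariance point opposite ways, so neither settles whether returns exceed those from the shared libraries. The simulations called 0.05 genes each as returning, against 264 in the data. No gene was changed in the simulations, so a count near 0 was set in advance. It cannot say how many of the 264 arose from the shared libraries. These calls rest on few libraries and on the fit: edgeR called 0 genes between the stages without outgrowth replicate 1 or 2 (1446 and 1694 at an unadjusted p below 0.05), 15 without initiation replicate 2 and 0 without the abundance trend (2997 at an unadjusted p below 0.05). With all libraries DESeq2 called 1822 and limma on log2(CPM + 1) called 1032.

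Initiation replicates 1 and 3 differed by less than counting noise. Independent libraries would differ by at least that noise, and the mean squared difference was 0.400 times it, which excludes independence. Replicate 1 had more reads than replicate 3 in 0.220% of 20496 genes, 45 genes by at most 2 reads. So few genes are what shared reads would give, in which replicate 3 holds those of replicate 1 and more. A random part of replicate 3 would differ from it by 0.297 times the noise on average, less than the 0.400 seen. Exact nesting is thus not shown. No biological explanation was tested.

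Many genes counted well in control replicate 2 were absent from control replicate 1. Of 17559 genes with at least 10 reads expected there, 699 had none, where Poisson sampling gives 0.0075, so lower depth does not account for them. In reverse, 136 of 17583 such genes were absent from control replicate 2, where Poisson sampling gives 0.0013. Between the outgrowth libraries 8 and 39 genes were absent in this way, and between initiation replicates 2 and 3, 422 and 214. A candidate explanation is few starting molecules. Set from genes with 5 to 20 expected reads, 10.9 reads per molecule predicts 142 absent genes at 20 to 100 expected reads. There were 310, a ratio of 2.19, inside the limit of 3 set before the test. That limit is wide and the prediction falls well short, so few starting molecules remain a candidate only. A difference in the captured tissue stays open and was not tested.

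Genes next to each other in locus number changed together more than in shuffled orders. Across 18812 genes the Spearman correlation of log2 fold changes of neighbours was 0.0651 for initiation with control, where the highest of 1000 shuffled orders gave 0.0238. It was 0.0651 for outgrowth with control and 0.0727 between the stages (permutation p = 0.001 for each of these 3, one-sided, also after adjustment, the smallest 1000 shuffles can give). Genes are not independent replicates. At a distance of 20 genes it was 0.0086 for initiation with control. Without the most strongly changed 10% of genes it was 0.0314 for initiation with control, above the highest shuffled 0.0278, so chance placement and a few strong clusters both leave a remainder. Reads divided between neighbouring copies, overlapping genes and shared regulation stay open as hypotheses and were not tested.

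Among 72 tests of chromosomes, the smallest p was for genes called higher at initiation on chromosome 6, 11.3% against 14.4% over all chromosomes (permutation p = 0.00599, adjusted p = 0.432, from 1000 rotations of the gene order), which does not pass the correction.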
